A study of Mus musculus with 8 samples.

How the data were processed

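The data are 8 samples of soleus muscle from male C57BL/6J mice aged 14 weeks that ate a high-fat diet, 4 from mice filed as given the oral bacterium Porphyromonas gingivalis and 4 from mice filed as given saline for 6 weeks, per the labels. Total RNA was extracted from muscle, 200 ng was labelled with the dye Cy3, and each sample was hybridised to 1 Agilent mouse array. The deposited spot intensity values, per the file headers, came from Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes list version 11.1. Per the file headers the probe positions refer to mouse build mm9. All 8 arrays lay on 1 slide and came from 1 scan. The arrays filed as P. gingivalis filled 1 side of that slide and the arrays filed as saline the other, so slide side and group cannot be told apart.

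Each array's processed signal, already background-subtracted per the file headers, was converted to log2 and the array's 75th percentile was subtracted. Control spots and spots with outlier flags were left out, which affected 239 probes on at least 1 array. Spots of 1 probe were averaged. Of 56605 probes, 33636 were kept because they were well above background on at least 4 arrays. Probes were named from RefSeq accession (32994 probes), current symbol (10224) or older symbol (520) in a table of assembly GRCm38.p6 used for names alone, and 12867 kept the name in the files. Each of the 22221 genes was represented by its kept probe with the highest mean signal.

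Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, tests two-sided), with Benjamini-Hochberg adjustment over all 22221 genes. On data simulated for this comparison over the 22221 genes, 46% of genes changed by 0.5 on the log2 scale were recovered, 80% at 1, 96% at 2 and 100% at 3, with 3 false calls. Genes were drawn independently from normal distributions, with no background floor and no effect of array or slide side. These rates may therefore not hold for the real arrays. Another 43 gene lists, 28 of pathways and 15 of cell type markers, were compared by limma's camera with a preset correlation of 0.01. In simulated data, with each gene drawn independently, the 1 shifted list was called and 0 others were. That simulation holds no correlation between genes, so it does not test the preset value. List means per array were compared by an exact permutation test over the 70 assignments, a test chosen after the data had been seen.

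The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 named genes per direction, by size, among genes with adjusted p under 0.05 and groups that did not overlap. Free places went to genes with the smallest p among those differing at least 1.5-fold and well above background on all 8 arrays, reported as not past the threshold. It added 16 fixed genes of insulin signalling, inflammation and atrophy, 4 members of each list past the threshold, and 2 members of each other list discussed. Of the genes the rule named, 3 are not reported here. The 5 other lists discussed were chosen after list results had been seen. For a gene below background on all arrays of a group, the fold is a bound, taken against the higher of the lowest well-measured signal and the gene's own signal on each array. Such a bound holds for this processing.

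A deposited table of the series, in log2 values with p-values per the authors, gives 28250 rows. Its moderated statistic and log odds columns, each a score by the deposited column names, were not used. Its values were rebuilt from the scanner files by limma's normexp with an offset of 16 on median signals, quantile normalization on the linear scale, a filter at 1.1 times the 95th percentile of the negative controls on at least 4 arrays, and averaging per accession. The greatest difference was under 1e-06 on the log2 scale, and these steps are those that gave equal values, not steps that a header records. Each of its 8 columns equalled the array filed under the other group with the same replicate number, and 0 equalled the array of its own name. Groups were taken from the sample records, and which source is right is not settled.

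Arrays correlated within groups at 0.989 to 0.995 and between groups at 0.989 to 0.992, and 0 arrays were identical. The 75th percentile of the signal was 648 to 764, the lowest in P. gingivalis 2, whose extraction status was to be evaluated per the file headers, while the other 7 arrays were in range. The number of arrays limits the precision. Alternatives covered background correction, scaling, the filter on dim probes, the probe rule, the replicate number as a block, variance models, array weights, thresholds, set tests and each array left out.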

Results

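Gene expression in the slow soleus muscle was measured in 8 samples from high-fat-fed male mice, 4 filed as P. gingivalis, a bacterium of human gum disease given by mouth, and 4 filed as saline, to ask how the bacterium changes muscle expression. The groups lay on opposite sides of 1 slide, so every difference below is also one between the sides. The labels give 1 array per sample and random division of mice, without stating that each array came from a separate mouse, so p-values measure the spread between these samples. Between 30177 and 34075 probes were well above background on the arrays filed as saline and between 34852 and 35365 on those filed as P. gingivalis (exact permutation p = 0.0286). The median net signal was 94.9 ± 4.6 (SD, n = 4) and 84.4 ± 3.74 (SD, n = 4) in arbitrary units (exact permutation p = 0.0286).

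Between the groups, 26 of 22221 genes differed at an adjusted p under 0.05. They were headed by Slc18a1, a vesicular monoamine transporter, in this processing at least 7.82-fold lower in the arrays filed as P. gingivalis. It was not well above background on any of those 4. Slc18a1 had an adjusted p of 0.00105 in limma's fit. Its probe lies on chromosome 8 from 71589069 to 71589128 in build mm9. This direction opposes that in the authors' deposited table, whose columns carry the groups the other way round, with a log2 difference of 1.45 for Slc18a1. In size, 1.45 is below the main fit's bound of 2.97 on the log2 scale, so that bound depends on the processing. The authors' deposited table lists 431 of 28250 rows with adjusted p under 0.05, 110 higher and 321 lower in the columns named P. gingivalis. Every direction below follows the sample records and would be turned if the table's columns were right. Dixdc1, a Wnt pathway protein, was lower by a log2 difference of -0.88 ± 0.05 (SE, n = 4 and 4), adjusted p = 0.00105, and well above background on all 8 arrays (probe on chromosome 9 from 50517818 to 50517877).

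Of the 26 genes, 8 were higher and 18 lower in the arrays filed as P. gingivalis, or 18 higher and 8 lower with the table's groups. Gucy2g, a guanylate cyclase, and Gabrg3, a GABA receptor subunit, fell to signals not well above background on all 4 arrays filed as P. gingivalis and were at least 4.61-fold and 4.83-fold lower in this processing. In the authors' deposited table their log2 differences were 1.40 and 1.18 in size, below these bounds of 2.21 and 2.27 on the log2 scale. Plk2, a polo-like kinase (-0.68), Rttn, a centrosome protein (-0.69), Cnksr2 (-0.45), Fmnl3, an actin-regulating formin (-0.44), Snx1, an endosomal sorting nexin (-0.44), and Mapt, the microtubule protein tau (-0.41), also fell on the log2 scale, each with adjusted p between 0.0371 and 0.0467. Sec14l1 rose by 0.57, the zinc finger gene Zfp946 by 0.49 and Zfp592 by 0.49, with adjusted p of 0.0371, 0.0400 and 0.0467. Other kept probes differed in sign for Gabrg3 (up to 0.13), Rttn (up to 0.02) and Snx1 (up to 0.26). With the same sign but near 0 were another Sec14l1 probe (0.05) and the weakest of 5 Mapt probes (-0.0046).

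**Figure D1:**
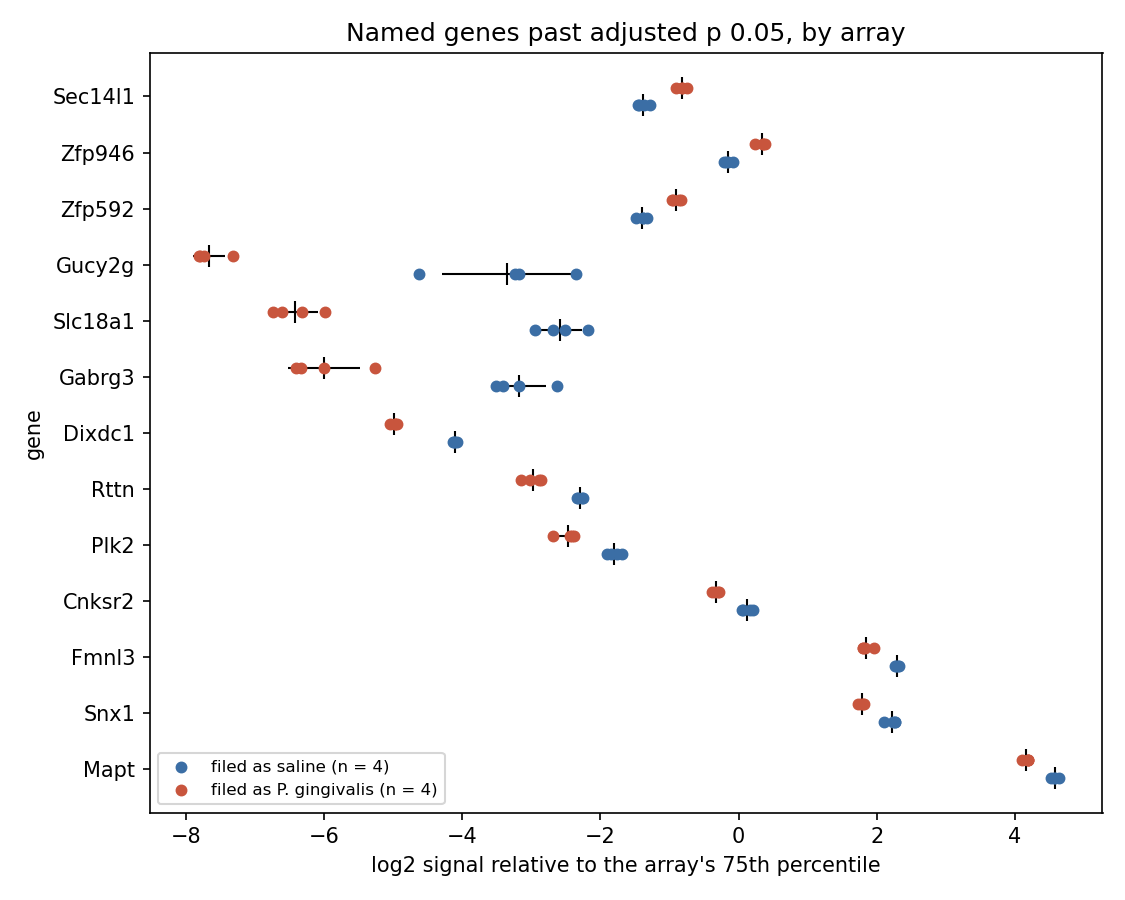
Log2 signal relative to each array's 75th percentile (x axis) for the 13 named genes with adjusted p under 0.05 (y axis); points are arrays, filed as saline (blue, n = 4) or P. gingivalis (red, n = 4), and black marks with bars are the mean and SD. Groups do not overlap for any of the 13, and Slc18a1, Gucy2g and Gabrg3 have the widest gaps, with red points that were not well above background.

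Of the 26 genes, 6 differed at least 2-fold, all lower, and 5 of these were not well above background on any array filed as P. gingivalis. At an unadjusted p under 0.05 there were 4383 genes, 19.72% of those tested, with 2236 higher and 2147 lower. Groups did not overlap for 2982 genes (13.42%, against 2.857% by chance). Among genes that did not pass the threshold, Gsta3, a glutathione transferase, had a log2 difference of 1.22 ± 0.17 (SE), adjusted p = 0.0572, and Nfil3, a circadian repressor, 0.83 ± 0.17 (SE), adjusted p = 0.0781. Adora2b, an adenosine receptor (0.81), Asb15 (0.84), Dnmt3l (0.76, with another probe at -0.60), Chka, a choline kinase (0.67), Olfr190 (0.65), Prr30 (0.64) and Platr25 (0.60) had adjusted p of 0.0578 to 0.0843. Klf4, a transcription factor, was at -0.76 ± 0.10 (SE), adjusted p = 0.0556, and Gria1, a glutamate receptor subunit, at -3.02 ± 0.43 (SE), adjusted p = 0.0572, with another probe at 0.03.

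Leaving out any 1 array left 2 to 6 genes past the threshold: 5, 2, 6 and 3 without saline 1 to 4, and 2, 2, 3 and 3 without P. gingivalis 1 to 4. With the replicate number as a block, 0 genes passed by limma. The split was 152 higher and 64 lower under quantile normalization, 57 and 34 under median centring, and 271 and 182 with normexp background correction, with more genes higher under each of these. It was 512 higher and 4642 lower with no filter on dim probes, and 2 and 7 with the mean of all probes.

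Of the 16 fixed genes of insulin signalling, inflammation and atrophy, 15 were measured and 0 passed the threshold in limma's test. Slc2a4, the insulin-responsive glucose transporter, differed by 0.06 ± 0.06 (SE) on the log2 scale, adjusted p = 0.631. Irs1, an insulin receptor substrate, was at -0.35 ± 0.13 (SE), adjusted p = 0.198, and Irs2 at -0.16, Insr at 0.15, Akt2 at 0.03, Tbc1d4 at 0.08, Hk2 at 0.20, Pdk4 at 0.04 and Ppargc1a at 0.36. The inflammatory genes Tnf (-0.05), Ccl2 (-0.60), Socs3 (-0.19) and Nfkbia (0.11) and the atrophy ligases Trim63 (0.29) and Fbxo32 (-0.10) also did not pass, and another Trim63 probe was at -0.52. With 1 array left out, 13 of these 15 values moved by over 1.5 times, all but Irs1 (-0.45 to -0.26) and Hk2 (0.13 to 0.25). The ranges were 0.03 to 0.10 for Slc2a4, -0.24 to -0.05 for Irs2, 0.09 to 0.19 for Insr, 0.02 to 0.15 for Tbc1d4, 0.25 to 0.56 for Ppargc1a, 0.05 to 0.17 for Nfkbia, 0.15 to 0.40 for Trim63 and -0.16 to -0.06 for Fbxo32. Ccl2 ranged from -1.11 without P. gingivalis 3 to -0.08 without saline 1, Socs3 from -0.47 without P. gingivalis 3 to -0.04 without P. gingivalis 1, and Tnf from -0.33 without saline 2 to 0.55 without saline 4. Akt2, Pdk4 and Tnf took the other sign under at least 1 alternative. Il6 was not kept, since 1 probe was well above background on 2 arrays filed as P. gingivalis and 0 filed as saline, and its other probe on 0.

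Of the 43 gene lists, 11 passed an adjusted p of 0.05 by camera, 8 higher and 3 lower in the arrays filed as P. gingivalis, or 3 higher and 8 lower with the table's groups. None of the 11 passed with an estimated correlation, where each had adjusted p = 0.890 with an estimated correlation. Interferon-stimulated genes had the lowest p: 36 of 38 measured members were lower, the median log2 difference was -0.37 and the adjusted p was 2.55e-05, but adjusted p = 0.890 with an estimated correlation and 0.420 by fry. Members of this list included Ddx58, an RNA sensor, at -0.42, Mx2 at -0.67 and Gbp4 at -0.79, with 0 members past the threshold over all genes or adjusted over the list alone. Its median was -0.21 without saline 2. Neutrophil markers had a median of -0.24 (adjusted p = 0.0221), with 10 of 11 lower, among them S100a8 (-2.21), S100a9 (-2.10) and Csf3r (-0.24). The Csf3r probe, whose difference is the list median, had a mean log2 signal of 6.26 in the arrays filed as saline, against -2.17 for S100a8. Whether so bright a probe reports neutrophils was not tested. Cxcr2, also lower, was well above background on 3 arrays filed as saline and 1 filed as P. gingivalis. S100a9 stood at 1.13 and 0.66 in saline 1 and 2, against -2.27 and -2.01 in saline 3 and 4 and -2.97 to -2.24 in the arrays filed as P. gingivalis. S100a8 stood at -0.69 and -1.13 in saline 1 and 2, and saline 3, at -4.30, lay between P. gingivalis 2 (-4.28) and P. gingivalis 4 (-4.58). The endothelial and neutrophil calls were lost as well, each with adjusted p = 0.890 with an estimated correlation. Endothelial markers had a median of -0.13 (adjusted p = 0.0389), with 11 of 15 lower, such as Egfl7 at -0.40, Kdr, a vascular growth factor receptor, at -0.55, Ptprb at -0.29 and Vwf at -0.33, and 3 members adjusted over the list alone. The other 4 were higher, among them Pecam1 and Tie1 at 0.18 each, named after their values were seen.

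Genes of fuel use and contraction made up most of the higher lists. These 8 lists were also brighter than the 3 lower ones. Their mean log2 signals in the arrays filed as saline were 2.99 to 7.31, against -1.47 to 2.43. Bright lists of ribosomal proteins (6.69) and heat shock proteins (5.41) did not pass. Whether list direction follows signal level was not tested. Each of the 8 higher lists passed by camera with the preset correlation alone, and had adjusted p = 0.890 with an estimated correlation. For the citric acid cycle the median was 0.11 (adjusted p = 0.000177), with 24 of 26 members higher, such as Pdp1 (0.51), Pdha1 (0.21, but -0.10 with all probes averaged) and Dld (0.20), and 2 members adjusted over the list alone. Fatty acid oxidation had a median of 0.11 (adjusted p = 0.00293), with Crat (0.32), Slc27a1 (0.31), Slc27a4 (0.27) and Hadh (0.24), and 3 members adjusted over the list alone. Respiratory chain genes had a median of 0.06 (adjusted p = 0.00359), with Ndufv2 at 0.21, Ndufa10 at 0.12, Atp5b at 0.19 and Cox5a at 0.13, and glycolysis a median of 0.06 (adjusted p = 0.0389), with Fbp2 at 0.38, Pygm at 0.22, Pfkm at 0.23 and Pfkfb1 at 0.50. With all probes averaged, Ndufv2 was at -0.11 and Ndufa10 at -0.02. Fast fibre genes had a median of 0.17 (adjusted p = 0.000154), with 19 of 20 higher, such as Atp2a1, the fast calcium pump, at 0.50, Ckm at 0.23 and Tpm1 at 0.19, and 1 member adjusted over the list alone. Slow fibre genes had a median of 0.10 (adjusted p = 0.00717), with Mb, myoglobin, at 0.32, Myl3 at 0.20, Tnnc1 at 0.19 and Myl2 at 0.21, and 1 member adjusted over the list alone. Glucocorticoid targets had a median of 0.24 (adjusted p = 0.00295), with Tsc22d3 at 0.54, Klf15 at 0.39, Cebpb at 0.30 and Angptl4 at 0.51, and this median was 0.15 without P. gingivalis 1 and 0.38 without saline 3. Red blood cell markers had a median of 0.57 (adjusted p = 0.0158), with Hba-a1 at 0.57, Hba-a2 at 0.57, Hbb-b1 at 0.88 and Bpgm at 0.32, and this median was 0.28 (adjusted p = 0.168) without saline 3 and 0.93 without saline 4.

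Beside the fibre lists, markers of the neighbouring fast muscles were uneven between arrays, with saline 1 at -0.94 and P. gingivalis 3 at -0.49 from the mean over the 8 arrays. Without these 2 arrays, chosen after the data had been seen, 0 genes passed by limma, with 3072 at an unadjusted p under 0.05, and 12 lists passed, 6 higher and 6 lower. Lost were slow fibre genes (adjusted p = 0.0604), red blood cell markers (0.157, median 0.39) and neutrophil markers (0.0801), and gained were collagen and matrix genes (0.000998), inflammatory response genes (0.0278), targets of TNF and NF-kB (0.027) and macrophage markers (0.0476). With an estimated correlation 0 of the 43 lists passed, the smallest adjusted p being 0.890 with an estimated correlation, and 0 passed by fry, the smallest adjusted p being 0.156. Under quantile normalization 2 lists passed, 0 higher and 2 lower, and the respiratory chain list turned to a median of -0.05 (adjusted p = 0.0632). Medians there were 0.01 for slow fibre genes (adjusted p = 0.92), 0.02 for glycolysis (0.865), 0.09 for fast fibre genes (0.175), 0.05 for fatty acid oxidation (0.311) and 0.07 for the citric acid cycle (0.138). Glucocorticoid targets (0.0632) and red blood cell markers (0.0992) also lost their calls there. With the table's processing rebuilt, calls were lost for slow fibre genes (median 0.0041, adjusted p = 0.856), fast fibre genes (0.09, 0.258), glycolysis (0.06, 0.311), respiratory chain genes (-0.03, 0.311), fatty acid oxidation (0.11, 0.06) and red blood cell markers (0.52, 0.105). Calls were gained there for collagen and matrix genes (-0.11, 0.0181) and targets of TNF and NF-kB (-0.13, 0.0366). List means per array gave 4 lists at an exact permutation p of 0.0286, the smallest the 70 assignments allow, and 0 after adjustment (smallest 0.307). Neutrophil markers lost their call with probes well above background on all 8 arrays (adjusted p = 0.0932), with no filter on dim probes (0.124), under quantile normalization (0.0632), without the same 2 arrays (0.0801) and without saline 1 (0.0501). With 1 array left out, calls were also lost for slow fibre genes without saline 1 (adjusted p = 0.062). Respiratory chain genes lost theirs without saline 2 (0.0894, median 0.036) or P. gingivalis 2 (0.0707, median 0.040). Red blood cell markers also lost theirs without saline 1 (0.0587) or P. gingivalis 3 (0.0519). Endothelial markers lost theirs with no filter on dim probes (adjusted p = 0.596) and with the replicate number as a block (0.084). They also lost it without saline 2 (0.0576), saline 4 (0.122), P. gingivalis 1 (0.245) or P. gingivalis 2 (0.0892), and had a median of -0.21 without P. gingivalis 4. Glycolysis lost its call with that block (0.0603) and with the mean of all probes (0.0529). The same held without saline 1 (0.0941), saline 2 (0.0584), saline 4 (0.0752) or P. gingivalis 2 (0.296, median 0.022).

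**Figure D2:**
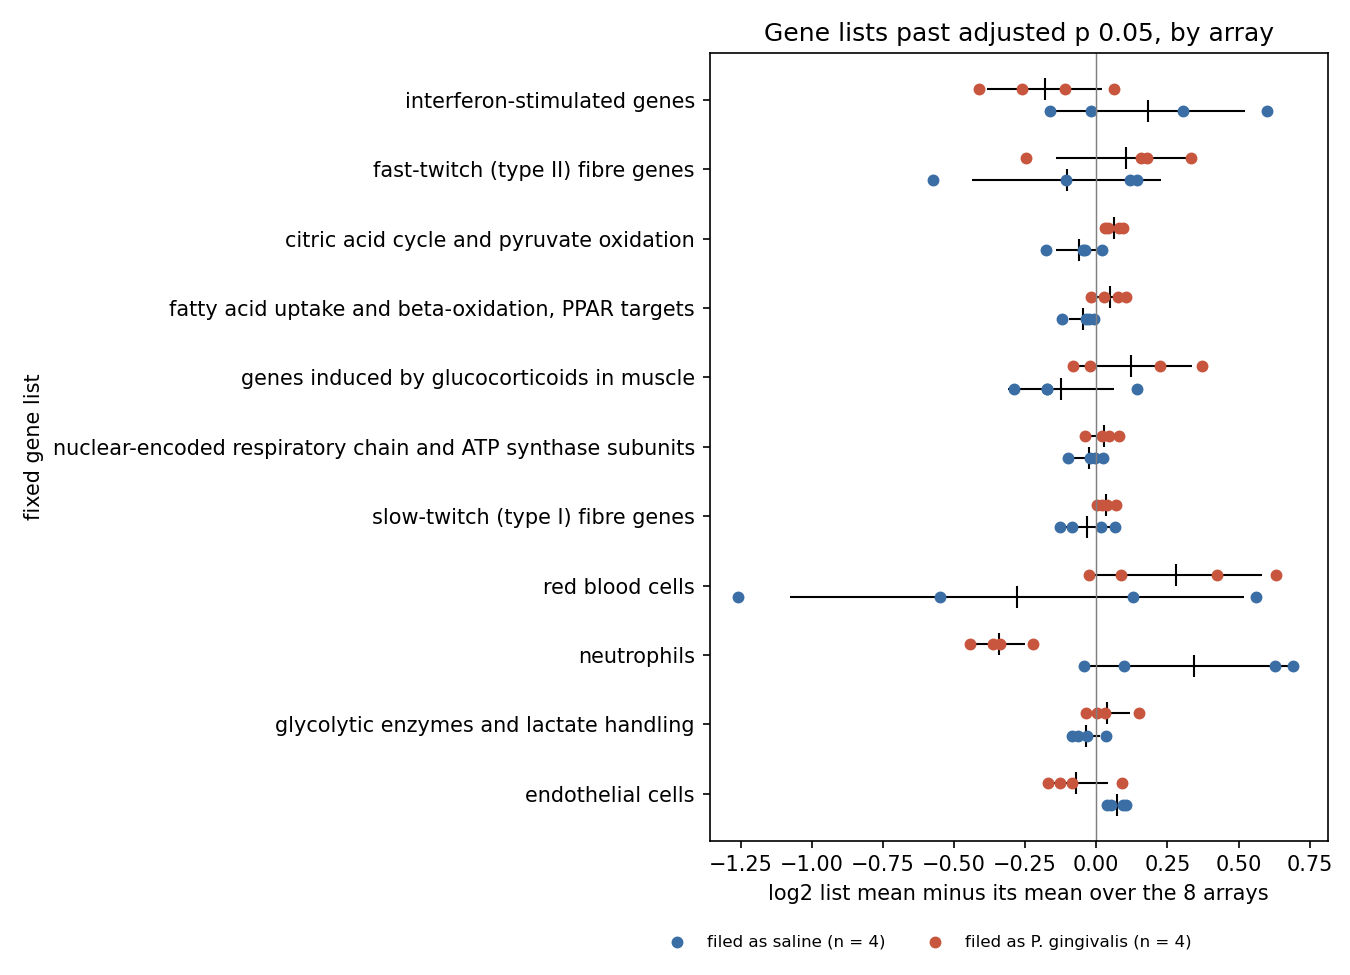
Mean log2 signal of each of the 11 gene lists past adjusted p 0.05, less its mean over the 8 arrays (x axis), by list (y axis); points are arrays, filed as saline (blue, n = 4) or P. gingivalis (red, n = 4), and black marks with bars are the mean and SD. Groups overlap for most lists, and saline 3 is at -1.26 for red blood cell markers.

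Lists of insulin signalling, inflammation, matrix and macrophages did not pass in the main fit. Under median centring, collagen and matrix genes (adjusted p = 0.0413), inflammatory response genes (0.0301) and targets of TNF and NF-kB (0.0413) passed by camera. Targets of TNF and NF-kB also passed with normexp (0.0343), and collagen and matrix genes with the mean of all probes (0.0204) and with array weights (0.0268). Inflammatory response genes passed with array weights (0.0264) and with trended and robust variance (0.0446). Insulin signalling passed with no filter on dim probes (0.00785). Macrophage markers passed under none of these settings. For insulin signalling 29 of 48 members were higher, with a median of 0.04 (adjusted p = 0.448), Foxo3 at 0.30 and Ppp1r3a at 0.33. Inflammatory response genes had a median of -0.25 (adjusted p = 0.0544), with Icam1 at -0.72, and targets of TNF and NF-kB a median of -0.15 (adjusted p = 0.0795). Collagen and matrix genes had a median of -0.10 (adjusted p = 0.0795), with Lox at -0.50 and Ccn2 at 0.22, and macrophage markers -0.33 (adjusted p = 0.185), with Cx3cr1 at -0.83 and Ms4a7 at -0.81. Without saline 3 or without P. gingivalis 3, each of these lists but insulin signalling passed. Medians moved away from 0 for collagen and matrix genes, to -0.17 without saline 1, -0.19 without saline 3 and -0.17 without P. gingivalis 3 or 4, for targets of TNF and NF-kB, to -0.23 without saline 3, and for macrophage markers, to -0.56 without saline 3. Collagen and matrix genes also passed without saline 1 (adjusted p = 0.0177) or P. gingivalis 4 (0.0152), and inflammatory response genes without P. gingivalis 4 (0.0316). With other arrays left out medians came nearer to 0: macrophage markers to -0.14 without saline 2 and -0.17 without saline 4, collagen and matrix genes to -0.04 without P. gingivalis 1 and -0.05 without saline 4, inflammatory response genes to -0.14 without P. gingivalis 1, and insulin signalling to 0.02 without saline 2.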

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

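Tests of a single array, of macrophage number, of the spike-in transcripts, of bright genes and of the table's labels were chosen after the results they bear on had been seen. Among 206 groups of 4 values, 8 held 1 array far from the other 3 (chance gives about 1 in 20, or 10.3). In the arrays filed as P. gingivalis, the log2 signals standing apart were Gucy2g at -7.32 in P. gingivalis 2, Fmnl3 at 1.96 in P. gingivalis 3, Mapt at 4.10 and Pdp1 at 2.03 in P. gingivalis 4, and Hadh at 5.87 and Mb at 9.44 in P. gingivalis 2. In the arrays filed as saline they were Mx2 at -2.44 in saline 2 and Atp2a1 at 6.45 in saline 3.

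Slc18a1, Dixdc1 and the other genes past the threshold were more than other groupings gave: 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, reached 26 genes, and the highest other split gave 3. A rank of 1 of 35 is the lowest that these splits allow, so chance is made less likely for that count but is not excluded. For the lists chance stays open, since 17 of the 35 splits gave at least the real 11 lists and the highest other gave 23. A share of 0.217 of genes in the brightest of 3 equal classes had an unadjusted p under 0.05, against at most 0.0822 in other splits. Bright genes thus also differed between the groups. Being bright by selection, they cannot show what background does to dimmer genes. This share does not test the 26 genes themselves, of which 5 were not well above background on any array filed as P. gingivalis. Without a filter on dim probes, 5154 genes passed. A common spike-in shift of -0.0931 between the sides of the slide was removed first, and, being common, it is not a measure of gene-to-gene differences. The absolute spike-in differences then had a median of 0.0284 and a 90th percentile of 0.0698 (interval 0.0535 to 0.0753 over 4 transcripts). The gene difference in excess of other splits, taken from medians, was 0.0743, inside that interval of a 90th percentile. A median and a 90th percentile are unlike measures, so this comparison decides nothing. Genes of the brightest class had a median absolute difference of 0.0902 and a 90th percentile of 0.245. The bacterium and the side of the slide cannot be told apart, because each group filled 1 side. This spike-in comparison replaced a planned one against whole gene differences, which hold the spread between samples.

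Interferon-stimulated genes were lower in the arrays filed as P. gingivalis, with a list median of -0.371. The 18 members brighter than the median gene had a median of -0.307 (interval -0.389 to -0.107), which, within these 8 arrays, argues against dim probes. Intervals in this paragraph come from resampling member genes, so they leave out the spread between samples. Without saline 2 the median was -0.211 (interval -0.296 to -0.144), so how much of it that array carries is open. Macrophage markers, which did not pass (adjusted p = 0.185), had a median of -0.33 (interval -0.633 to -0.149), with -0.14 without saline 2 and -0.56 without saline 3, and over the 8 arrays the deviations of both lists from their group means had a Pearson r of 0.857 (exact permutation p = 0.0278, adjusted 0.0912 over 5 relations), a Spearman rho of 0.857 (exact permutation p = 0.0312) and an r of 0.919 without the 2 farthest arrays. Whether this relation is particular to macrophage markers was not tested. Fibroblast markers, with a list median of 0.01, were also highest in saline 2 (0.24) and lowest in saline 3 (-0.35) among the arrays filed as saline. The interferon list stood there at 0.60 and -0.16. Fewer macrophages may account for the interferon list, as may another difference shared by several cell types, the bacterium, the side of the slide or chance. The interferon list's means per array gave an exact permutation p of 0.143 (adjusted 0.512).

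The groups are exchanged between the authors' deposited table and the sample records: 8 of its 8 columns equalled the array of the other group with the same number. Whether the records or the columns carry the wrong group cannot be told apart, since the array measures 0 transcripts that the design fixes between the groups. Slc18a1 and Gucy2g are lower with P. gingivalis under the records and higher under the table.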

How the results depend on the processing

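The rebuilt table, the exact test on list means and the fits without 2 arrays were chosen after the data had been seen. The count of 26 genes became 453 with normexp background correction, 216 under quantile normalization, 91 under median centring, 5154 (of 36895) with no filter on dim probes, 261 with probes well above background on all 8 arrays, 9 with the mean of all probes, 567 with trended and robust variance, 199 with array weights and 362 with the table's processing rebuilt. It was 727 at an adjusted p under 0.1, 6 with at least 2-fold, 4383 at an unadjusted p under 0.05 and 2 to 6 without 1 array. Without saline 1 and P. gingivalis 3 it was 0, by limma, with 3072 at an unadjusted p under 0.05. Of the 26 genes, 25 also passed with normexp, 26 under quantile normalization, 26 with trended and robust variance, 20 with probes well above background on all 8 arrays and 20 with the table's processing rebuilt. The count of 11 lists became 2 under quantile normalization, 7 with the table's processing rebuilt, 0 with an estimated correlation, 0 by fry, 0 by the exact permutation of list means and 8 to 16 without 1 array. With the replicate block 0 genes passed by limma (4432 at an unadjusted p under 0.05) and 9 lists. Deviations from the group means of each gene correlated between samples with the same number at 0.0639, -0.0577, -0.0406 and 0.231. Only the samples numbered 4 were each other's closest match by row. The numbers were therefore not taken to pair the samples, although arrays with the same number share a slide position. Block by slide was not run, as there is 1 slide, and a block by slide position equals the replicate block. The cause was not tested, except where fewer arrays or other probes or thresholds entered by construction.

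Signs turned for Cox5a (-0.0031) and Pdk4 (-0.068) under quantile normalization, for Ndufa10 (-0.0197), Ndufv2 (-0.11) and Pdha1 (-0.10) with the mean of all probes, for Myl2 (-9.8e-06) and Pdk4 (-0.12) with the table's processing rebuilt, and for the respiratory chain list (-0.046 under quantile normalization and -0.028 with the table's processing rebuilt). Leaving out 1 array turned Akt2 (-0.00033 without saline 2, range up to 0.0449), Pdk4 (-0.00045 without saline 4, -0.0038 without P. gingivalis 1, range up to 0.0636) and Tnf (0.55 without saline 4, 0.049 without P. gingivalis 2). Of the 24 named genes and lists past the threshold, 10 to 15 lost their call with 1 array left out and 0 turned. Signal over background limits Gucy2g, Slc18a1 and Gabrg3 to bounds, which hold for the main processing and exceed the differences in the authors' deposited table.

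With the authors' deposited table as input, 362 genes passed (98 higher and 264 lower) and 7 lists (5 higher and 2 lower), and 100 of the 103 named genes and lists took the opposite sign, by the exchange of its column names. Log2 differences of genes, columns named P. gingivalis minus columns named saline, were Adora2b -0.75, Akt2 -0.14, Angptl4 -0.44, Asb15 -0.78, Atp2a1 -0.45, Atp5b -0.14, Bpgm -0.27, Ccl2 0.50, Ccn2 -0.22, Cebpb -0.26, Chka -0.68, Ckm -0.15, Cnksr2 0.36, Cox5a -0.038, Crat -0.34 and Csf3r 0.23. Further values were Cx3cr1 0.49, Cxcr2 0.41, Ddx58 0.32, Dixdc1 0.32, Dld -0.23, Dnmt3l -0.71, Egfl7 0.40, Fbp2 -0.33, Fbxo32 0.18, Fmnl3 0.47, Foxo3 -0.32, Gabrg3 1.18, Gbp4 0.76, Gria1 1.83, Gsta3 -1.05 and Gucy2g 1.40. Further values were Hadh -0.26, Hba-a1 -0.48, Hba-a2 -0.43, Hbb-b1 -0.87, Hk2 -0.17, Icam1 0.69, Insr -0.18, Irs1 0.38, Irs2 0.19, Kdr 0.59, Klf15 -0.41, Klf4 0.84, Lox 0.35, Mapt 0.25, Mb -0.10 and Ms4a7 0.64. Further values were Mx2 0.39, Myl3 -0.037, Ndufa10 -0.10, Ndufv2 -0.24, Nfil3 -0.80, Nfkbia -0.085, Olfr190 -0.58, Pdha1 -0.18, Pdp1 -0.47, Pfkfb1 -0.54, Pfkm -0.16, Platr25 -0.59, Plk2 0.53, Ppargc1a -0.33, Ppp1r3a -0.30 and Prr30 -0.64. Further values were Ptprb 0.35, Pygm -0.25, Rttn 0.44, S100a8 1.67, S100a9 1.83, Sec14l1 -0.52, Slc18a1 1.45, Slc27a1 -0.32, Slc27a4 -0.27, Slc2a4 -0.089, Snx1 0.14, Socs3 0.28, Tbc1d4 -0.081, Tnf 0.036, Tnnc1 -0.20 and Tpm1 -0.018. Further values were Trim63 -0.30, Tsc22d3 -0.48, Vwf 0.31, Zfp592 -0.48 and Zfp946 -0.47. List medians were collagens and extracellular matrix 0.11, endothelial cells 0.12, red blood cells -0.52, fast-twitch (type II) fibre genes -0.094, fatty acid uptake and beta-oxidation, PPAR targets -0.11, genes induced by glucocorticoids in muscle -0.30, glycolytic enzymes and lactate handling -0.0609, receptors and mediators of inflammation, including toll-like receptors 0.12, insulin receptor signalling to glucose transport and glycogen -0.045, interferon-stimulated genes 0.26, macrophages 0.23, neutrophils 0.14, slow-twitch (type I) fibre genes -0.0041, citric acid cycle and pyruvate oxidation -0.11 and targets of TNF and NF-kB signalling 0.13.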

Other observations

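The correlations between lists were chosen after the results had been seen. The other 32 lists had adjusted p of 0.0544 to 0.946 by camera and medians between -0.33 and 0.16 on the log2 scale. Immediate early genes had 8 of 27 members adjusted over the list alone, 4 of them higher, with a list median of -0.15 (adjusted p = 0.236). Ribosomal protein genes had a median of 0.03 (adjusted p = 0.242), circadian clock genes -0.03 (adjusted p = 0.894) and atrophy genes 0.07 (adjusted p = 0.329). In 6 lists the median, the mean and the direction of the test differed in sign: denervation, lipogenesis, oxidative stress, circadian clock, white adipocytes and myokines.

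Among markers of cells other than muscle fibres that did not pass by camera, medians were -0.176 for Schwann cells (adjusted p = 0.230), -0.0975 for muscle stem cells (0.372), 0.0778 for pericytes and smooth muscle (0.409) and 0.0102 for fibroblasts (0.946). Over the 8 arrays the within-group deviations of 14 fast fibre genes, without the 6 that are also fast muscle markers, had a Pearson r of 0.748 with those of the fast muscle markers (exact permutation p = 0.0365, adjusted 0.0912 over 5 relations) and a Spearman rho of 0.833 (exact permutation p = 0.00694). Without the 2 farthest arrays r was 0.431. For the citric acid cycle list the corresponding r was 0.0571 (exact permutation p = 0.908, adjusted 0.908), rho 0.19 (exact permutation p = 0.736) and r 0.107 without the 2 farthest arrays. The citric acid cycle median was 0.114, and 0.137 under median centring and 0.0747 under quantile normalization.

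Interferon-stimulated genes and red blood cell markers had a within-group r of 0.692 (exact permutation p = 0.163, adjusted 0.272), rho 0.81 (exact permutation p = 0.0729) and r 0.623 without the 2 farthest arrays. Neutrophil and macrophage markers had an r of 0.353 (exact permutation p = 0.578, adjusted 0.722), rho 0.167 (exact permutation p = 0.757) and r -0.164 without the 2 farthest arrays.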
